A study of Mus musculus with 2 samples.

How the data were processed

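Testis DNA of C57BL/6 mice was sheared, and methylated fragments were pulled down with the MBD2 protein domain that binds methylated CpGs and then sequenced, per the labels. The series held 2 libraries, 1 from a wildtype testis and 1 from a testis of a Kaiso knockout male. Kaiso is the protein of the Zbtb33 gene, a zinc finger protein that binds methylated DNA. The knockout sample was labelled as generation 3 offspring and as sterile. The description of that sample contradicts itself, calling the testis wildtype while naming knockout mice as its origin. Samples were grouped by the genotype label, so each knockout value below rests on that label.

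Bowtie2 2.2.6, edgeR and the mm10 genome build were named in the submitters' processing notes. Both libraries were deposited in 1 table of 100 bp windows, whose column names are those of the MEDIPS package, per the file headers. The deposited count of a window is a whole number of reads, and the RPKM the authors gave is that count scaled to window length and library reads. The deposited counts and RPKM together gave 1 constant per library, read as the library size: 87710791 wildtype and 98549116 knockout reads. The authors' relative methylation score, whose scale is not stated, and the CpG count of each window were also deposited. The authors' log2 fold change was coded as wildtype over knockout and was turned round here, and it placed the knockout 0.13 higher than the RPKM ratio. The deposited p-value was below 0.05 in all 2537435 windows, each with a summed count of at least 10 and at least 1 CpG. The adjusted p-value of the authors was equal to the unadjusted one in all 2537435 windows. The table was therefore a list selected on an unadjusted p, and a window absent from it was not shown to be unchanged. Over 5000 sampled windows the deposited p-values had a Spearman rho of 0.998 with exact binomial tests on the counts, so they measure counting noise between 2 libraries. Another 10 columns of values per sample or per group were not used here.

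Ratios were computed as knockout over wildtype, scaled by library reads. Scaling by total autosomal counts had been planned, but the table holds part of each library, so that scaling became an alternative. The window counts of the table, 107010115 for wildtype and 145566310 for knockout, exceeded the reads, so a read was counted in several windows. Sums over windows were therefore divided by 4 to approximate fragments, a divisor chosen here, since the read extension is not given in the sources used here. Intervals are exact Clopper-Pearson 95% intervals of the conditional binomial and cover counting error only, as PCR copies are not independent molecules. A library without a whole fragment in a region was set to a floor of 3 fragments, or 12 window counts, and 3 counts in a single window. A fold written as at least some value is computed against that floor without the counting error of the other library, and the 95% interval, given beside it for genes, starts lower. The floor over regions was set in fragments after first values computed with 3 window counts had been seen. A region was called higher or lower in the knockout library with at least 20 fragments over both libraries, a ratio of at least 2 or at most 0.5, and an interval excluding 1.

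Regions were 1 kb bins, protein-coding genes and fixed gene lists. Gene positions came from the GRCm38.p6 annotation, the same assembly as mm10, given here as gene spans without strand, exons or sequence. Promoters could not be told from the other gene end, so gene-end regions, 1 kb on each side of both ends, took their place. The planned comparison of bins holding the Kaiso motif was not analysed here, because no genome sequence was used. For each of 20 gene lists the median log2 ratio was set against 10000 random lists of protein-coding genes matched on fragments in 20 classes, as a description of these libraries, and 21 of the 2018 genes stand in more than 1 list. The interval of a list median is the order-statistic interval over its genes. Bins with a mean of 3.5 or more CpGs per listed window (CpG-dense) were compared with bins at 1, the lowest value (CpG-poor).

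Genes were named by a rule. It took the 10 higher and 10 lower gene-end regions whose interval bound lay farthest from 0, without predicted or Riken symbols. It also took Zbtb33, up to 4 members of each list by the same bound, and the 5 longest runs of called bins per direction. The lists, this rule, the thresholds and most alternatives were fixed before the data were examined. Other scalings, minimums, folds and region definitions were tried. Calls were tested on simulated data, in which the totals of 14912 gene-end regions were redistributed between the libraries with 4 sizes of change. Of 50 regions changed 2-fold, 42.0% were called, of 50 changed 2.83-fold 82.0%, of 50 changed 4-fold 96.0%, and of 50 changed 8-fold 100%. Among 14712 unchanged regions 0.727% were called. The simulation left out the selection on p, so these shares are not error rates for regions of the selected windows. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3 and edgeR 4.0.16 for TMM factors.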

Results

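Methylated DNA of mouse testis was measured by MBD2 capture and sequencing in 1 wildtype library and 1 labelled as Kaiso knockout, whose sample description also calls its testis wildtype, to ask how methylation differs in the testis of males lacking Kaiso. The wildtype library held 87710791 reads and the knockout library 98549116. The deposited table listed 2537435 windows of 100 bp, 254 Mb in all, with a median of 39 wildtype and 40 knockout counts. Of these, 1432879 (56.5%) were higher and 1104556 (43.5%) lower in the knockout library. The table holds windows selected on an unadjusted p, so shares below are shares of listed windows, and ratios in them are pushed away from 1 by that selection. With 1 library per genotype the differences have no replicate check, and intervals cover counting error only.

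The targeted gene was read first, as a check of the labels. Zbtb33, on chromosome X from 38189793 to 38197046, had 16 listed windows with 303 wildtype and 83 knockout counts. The log2 ratio of knockout over wildtype was -2.04 (95% interval -2.80 to -1.31), and 15 of the 16 windows were lower in the knockout library. Most of these windows hold 1 or 2 CpGs. Lower listed windows with 1 and 2 CpGs had medians of -1.79 and -1.66 over the genome, so the ratio checks the label only weakly. A stretch of 5 adjacent windows, from 38192701 to 38193200, held no knockout count and 81 wildtype counts, between 11 and 20 per window. That stretch, picked because it held no knockout count, was at least 7.58-fold lower in the knockout library against the floor, without a counting interval. Runs of at least 5 adjacent listed windows without a knockout read numbered 202 in the genome, and 4 of them lay on X, while runs without a wildtype read numbered 1322. The mark read here is captured DNA and not RNA, and the deleted part of the allele was not given in the sources used here. Listed windows were absent within 1 kb of both ends of the gene. Under scaling within CpG classes the log2 ratio of Zbtb33 was -1.24.

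**Figure D1:**
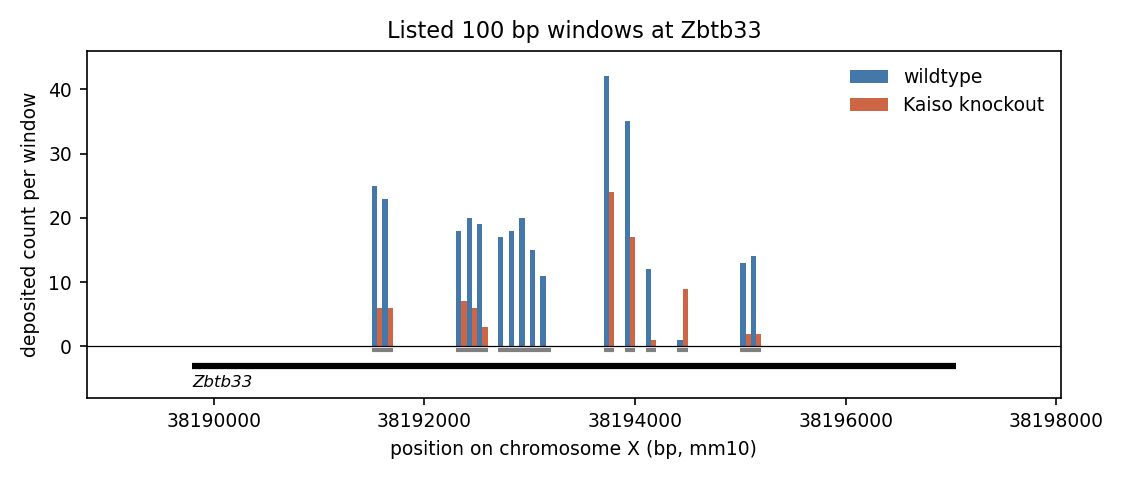
Deposited counts in the listed 100 bp windows of Zbtb33 (mm10), wildtype in blue and Kaiso knockout in orange, with grey marks under listed windows and the gene as a black bar. The 5 adjacent windows from 38192701 hold 81 wildtype counts and 0 knockout counts.

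The direction of a window followed its CpG content. Windows with 1 CpG were higher in the knockout library in 37.8% of 950757 cases (Clopper-Pearson interval 37.7 to 37.9%). Windows with 3 CpGs were higher in 71.0% (70.9 to 71.2%), and those with 5 or more, 227654 in number, in 98.9%. The size differed as well. Higher windows had a median log2 ratio of 0.69, and 68.8% of them lay under 2-fold, whereas lower windows had a median of -1.70. Median wildtype and knockout counts were 54 and 95 in higher windows, and 29 and 10 in lower ones. Low counts need a larger ratio to pass the selection on p, which may widen this difference in size and was not tested. Windows with 11 or more CpGs stood apart, with medians of 12 wildtype and 76 knockout counts, and 43.7% of them were at least 4-fold higher. The authors' relative methylation score had a median of 0.0093 in wildtype and 0.033 in the knockout in these windows. With 3 CpGs the medians were 0.137 and 0.150, with 5 CpGs 0.138 and 0.132, and with 6 CpGs 0.109 and 0.114, and from 3 to 10 CpGs the knockout median was the higher one in each class except 5.

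**Figure D2:**
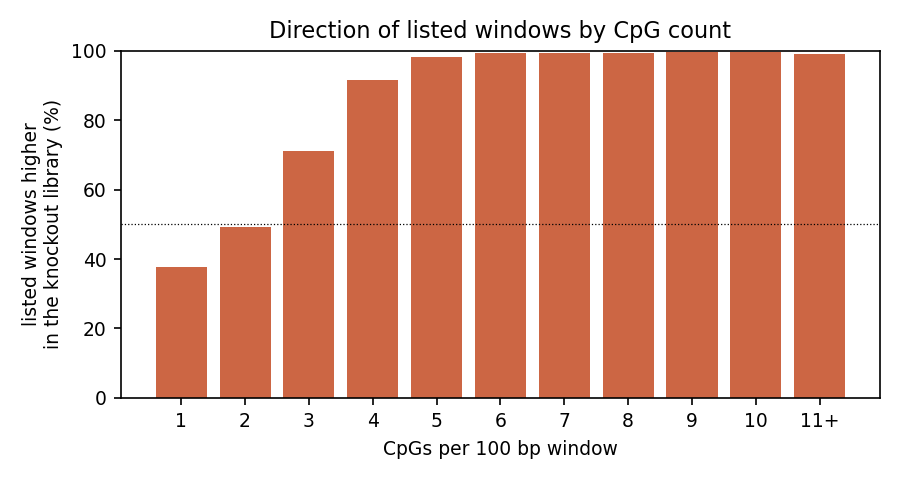
Percent of listed windows with more reads in the knockout library, by CpGs per 100 bp window, with a dotted line at 50%. The share is 37.8% with 1 CpG, 71.0% with 3 and 98.3% with 5.

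In 1 kb bins the CpG-rich and CpG-poor parts of the genome parted likewise. Over 86590 CpG-dense bins the log2 ratio was 0.66, and over 130910 CpG-poor bins it was -0.58, a difference of 1.25. Of 595994 bins with the minimum of 20 fragments, 66585 (11.2%) were higher and 150091 (25.2%) lower in the knockout library. Redistributing the bin totals by counting noise alone gave 3995 higher and 3813 lower bins. That redistribution left out the selection on p, which pushes ratios away from 1, so it likely understates the calls expected here without a change. The higher share of called bins was 30.7% with library reads, 33.1% with TMM and 39.2% with the authors' scaling. It was 21.2% with the autosomal counts of the file and 15.6% with the median of windows of 5 or more CpGs set to 0. Under scaling within CpG classes it was 84.1%, and the difference between dense and poor bins turned to -0.15.

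Counts in the listed windows of both sex chromosomes were higher relative to those of the autosomes in the knockout library. Wildtype medians were 20 counts per listed window on X and 14 on Y, against 37 to 43 on the autosomes. A window with fewer counts needs a larger ratio to be listed, so selection may push the X and Y ratios farther from 1. The intervals do not cover that, and it was not tested. The log2 ratio was 0.17 (0.16 to 0.18) for chromosome X and 0.23 (0.22 to 0.24) for chromosome Y. The share of listed windows higher in the knockout library was 64.8% on X and 84.1% on Y, against 52.4 to 60.0% on the 19 autosomes. Under scaling within CpG classes the ratio of X was 0.029 and that of Y 0.12, and without the 0.1% of windows with the highest counts that of Y was 0.41. Of 30 listed windows of the mitochondrial genome, 29 were lower in the knockout library, with 1668 wildtype and 768 knockout counts.

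The longest run of adjacent higher bins covered 45 kb of chromosome 8, from 123544001 to 123589000, over a cluster of 5S ribosomal RNA genes (log2 1.53, 1.46 to 1.60). The next lay on chromosome 6, without an annotated gene, from 114599001 to 114638000 (39 kb, log2 2.44), from 114565001 to 114598000 (33 kb, 2.68) and from 114526001 to 114554000 (28 kb, 1.99). A run of 26 kb on X started at 126746001 (log2 2.13). Lower runs were shorter. The longest covered 13 kb of X from 169970001 over Mid1, a gene that spans the edge of the pseudoautosomal region (log2 -1.72, -1.81 to -1.64). It was followed by runs of 9 kb on chromosome 13 from 66053001 (-1.86), 8 kb on Y from 90723001 (-1.62), and 7 kb and 6 kb on chromosome 13 from 65929001 (-1.96) and 66138001 (-2.29). Reads may be shared between copies in such repeated regions, as the handling of multiple alignments was not given in the sources used here.

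Around gene ends, higher regions were the more frequent. Of 21887 protein-coding genes 17019 had a listed window there and 14903 the minimum, of which 3350 (22.5%) were higher, 2004 (13.4%) lower and 9549 neither. The median log2 ratio was 0.50. This median and the split depend on the scaling. Of the called regions 62.6% were higher with library reads, 70.0% with the authors' scaling, 50.9% with autosomal counts, 45.5% with TMM and 38.2% with the median of windows of 5 or more CpGs set to 0, while scaling within CpG classes gave 92.8%. Those settings moved the gene-end median by 0.13, -0.27, -0.43, -0.67 and 0.33, so list medians below are to be read against 0.50.

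The highest regions were nearly free of wildtype reads. Irx1 and Foxc1, developmental transcription factor genes, had 0 wildtype counts and were at least 28.0-fold and at least 21.2-fold higher in the knockout library, with log2 intervals starting at 4.47 and 4.08. Tmem102 (at least 24.3-fold, interval from 4.27), Fndc5 (at least 20.5-fold, from 4.02) and the alpha globin gene Hba-a2 (at least 16.5-fold, from 3.71) had 0 wildtype counts as well. Atp6v0e2, a subunit gene of the vacuolar proton pump on chromosome 6 from 48537569 to 48541801, had 2 wildtype and 493 knockout counts, with an interval starting at a log2 ratio of 4.87. Kcnk12, a potassium channel gene, had 1 and 423, with an interval starting at 4.65. Myl9, a myosin light chain gene, had a log2 ratio of 6.41 (4.11 to 9.05), LOC102637806 of 5.83 (4.28 to 9.21) and Zfp385a of 5.21 (3.73 to 7.01). Over the whole gene the log2 ratio was 0.39 for Kcnk12, 0.71 for Zfp385a, 0.79 for Fndc5 and 1.03 for Myl9, and 6.10 for Irx1. With 500 bp on each side of the ends, and 0 wildtype counts set to the floor, it was 2.18 for Foxc1, 2.66 for Fndc5, 3.66 for Irx1, 3.91 for Tmem102, 4.32 for Kcnk12 and 5.66 for Myl9.

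The lowest regions held few windows, between 4 and 7 each, with 2 CpGs per window or fewer. Zfp444 had a log2 ratio of -5.47 (-10.83 to -2.93), Irx2 of -4.76 (-10.43 to -2.49), Mt4, a metallothionein gene, of -4.56 (-7.27 to -2.20), and Ifi27l2a of -4.52 (-10.23 to -2.26). Dmrtc1c1 (-4.29, -7.55 to -2.50) and Cbx5, the gene of heterochromatin protein HP1 alpha (-4.29, -7.40 to -2.34), followed. Pigv (-3.58) and the ribosomal protein gene Rpl29 (-3.39, -4.60 to -2.28) were lower too. Nop58 had 103 wildtype and 2 knockout counts, with an interval ending at -2.88, and Tbc1d32 had 78 and 2, with an interval ending at -2.47. Over the whole gene the log2 ratio was 0.80 for Zfp444, 0.34 for Dmrtc1c1, -0.037 for Irx2, -0.064 for Ifi27l2a, -0.079 for Cbx5, -0.086 for Tbc1d32, -0.16 for Pigv and -2.27 for Nop58. With 500 bp on each side of the ends it was 0.095 for Ifi27l2a, -1.54 for Irx2, -2.91 for Zfp444, -5.10 for Dmrtc1c1 and -5.15 for Cbx5.

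Imprinted genes whose promoters carry maternal methylation were higher in the knockout library nearly throughout. Of 19 with the minimum 18 were higher and 0 lower, with a median log2 ratio of 2.60 (2.08 to 3.35), at percentile 100 of random lists. Kcnq1ot1, a long noncoding RNA gene on chromosome 7, rested on 25 wildtype and 569 knockout counts (log2 4.34, 3.24 to 5.87). Ndn (3.94, 2.83 to 5.10), Mcts2 (3.75, 3.06 to 4.44) and Magel2 (3.54, 2.86 to 4.26) were alike. Kcnq1ot1 had 3.21 with 500 bp on each side of its ends and 1.09 over the whole gene, and Ndn had 4.55 with 500 bp. In the list of paternally methylated regions 2 of 7 were higher and 0 lower (median 0.73, percentile 82.9). These were Zdbf2 (2.82, 2.25 to 3.44) and Meg3 (2.46, 2.04 to 2.94), while H19 had 0.73 (0.45 to 1.02) and Dlk1 0.80 (0.40 to 1.22). Zdbf2 had 0.43 and Meg3 0.97 over the whole gene, both under 2-fold. With windows of 5 or more CpGs set to 0, 2 genes of this list were higher and 1 lower, and its median was 0.065. The regions of this list are gene ends and not the methylated control regions themselves.

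Germline genes that are methylated in somatic cells were higher in 31 of 38 and lower in 0, with a median of 2.42 (1.72 to 2.74, percentile 100). Dazl, an RNA-binding protein gene of germ cells on chromosome 17 from 50279393 to 50293620, averaged 4.12 wildtype and 58.6 knockout counts per window (log2 3.66, 2.93 to 4.40). Cyct, the testis cytochrome c gene (3.96, 3.12 to 5.02), Brdt (3.50, 2.89 to 4.13) and Sycp3, a gene of the synaptonemal complex (3.28, 2.73 to 3.92), were higher as well. In the 197 windows of this list with 5 or more CpGs the median RPKM was 0.798 in wildtype and 6.90 in the knockout, against 7.98 and 12.2 in all such listed windows. The medians of this list and of the maternally imprinted one stayed above 0 under each scaling tried, and over whole genes they were 0.73 and 1.09. Brdt had 0.48 and Cyct 1.18 over the whole gene.

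**Figure D3:**
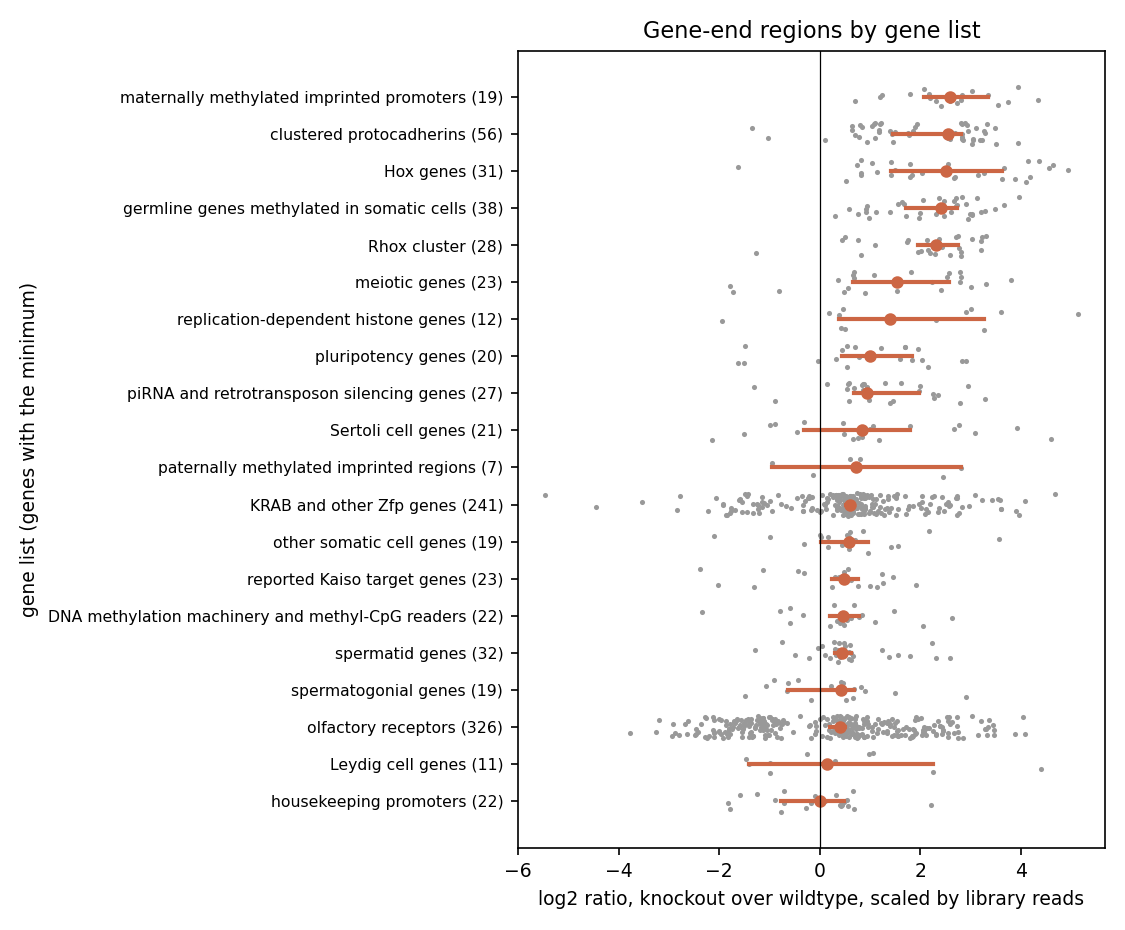
Log2 ratio of knockout over wildtype at gene ends for each gene with the minimum (grey points), with each list's median and its 95% order-statistic interval in orange. Maternally imprinted genes have a median of 2.60 and housekeeping genes of 0.0080, which is below 0 with TMM, autosomal counts, CpG classes or windows of 5 or more CpGs set to 0.

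Clustered developmental and X-linked families were higher at gene ends as well, and their medians stayed above 0 under each scaling tried. Over whole genes the medians were 2.31 for Hox, 1.64 for protocadherin and 2.01 for Rhox genes, against 0.73 for germline and 1.09 for maternally imprinted genes. Differences between these lists were not tested. Of 31 Hox genes 25 were higher and 1 lower (median 2.51, 1.42 to 3.62, percentile 100), among them Hoxd12 (4.64, 3.15 to 6.45), Hoxc6 (4.18, 3.18 to 5.29), Hoxa6 (4.15, 3.43 to 4.92) and Hoxa3 (4.10, 3.27 to 4.94). Of 56 clustered protocadherins 46 were higher and 2 lower (median 2.55, percentile 100). Genes of this list can share a gene end, so the same windows can count for several of them and the 56 are not independent. Pcdhb10 had 3.95 (2.92 to 5.35), and Pcdhga5, Pcdhgb1 and Pcdhga8 had 3.50, 3.48 and 3.33, though these last share 1 gene end and are not independent. Of 28 Rhox genes, a homeobox cluster on X, 23 were higher and 1 lower (median 2.31, percentile 100), with 3.22 for Rhox2a, 3.30 for Rhox2d, 3.22 for Rhox2h and 3.24 for Rhox10. Hoxa3 had 2.204, Pcdhga5 1.64, Pcdhgb1 1.72 and Pcdhga8 1.69 over the whole gene, and Pcdhb10 had 2.67 with 500 bp on each side. Reads may be shared between the Rhox2 copies.

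**Figure D4:**
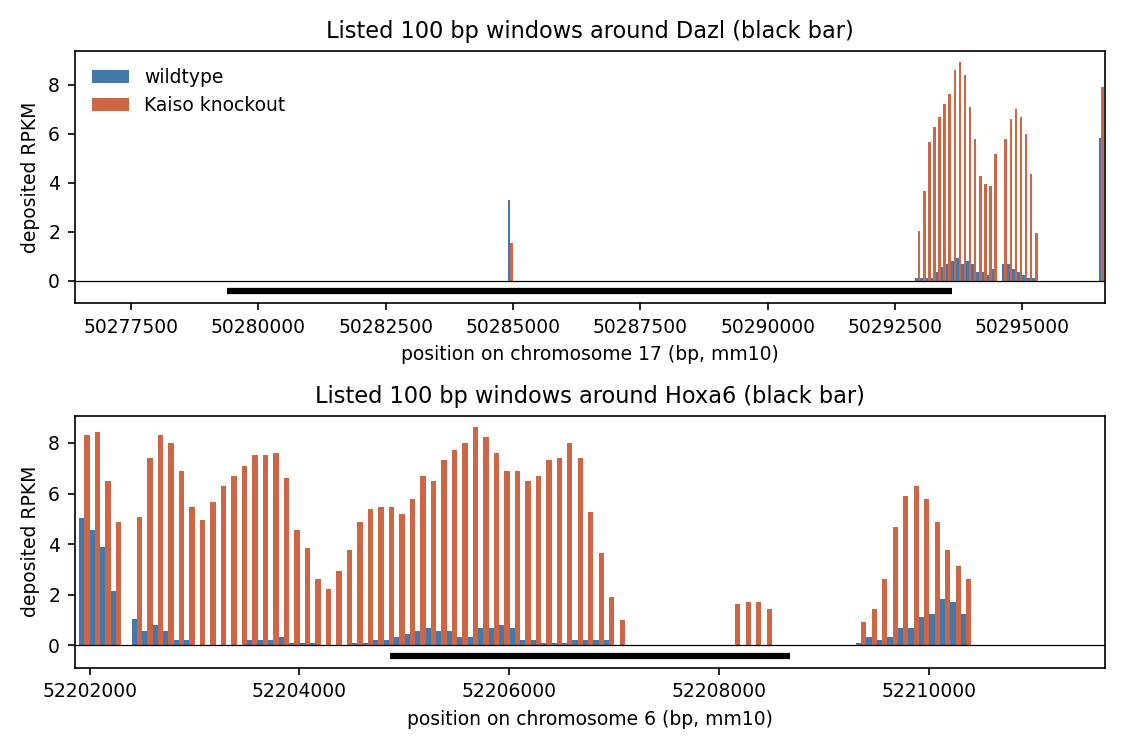
Deposited RPKM in listed 100 bp windows around Dazl and Hoxa6 (mm10), wildtype in blue and knockout in orange, genes as black bars, and blank stretches where no window was listed. Windows at the ends of Dazl averaged 4.12 wildtype and 58.6 knockout counts, and those of Hoxa6 2.31 and 46.1.

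Differences between the lists of spermatogenesis stages were not tested. Meiotic genes had 13 of 23 higher and 2 lower (median 1.54, 0.67 to 2.57, percentile 100), with Rnf212 (3.32, 2.69 to 4.09), Ccnb1ip1 (3.02), Sycp2 (2.80) and Hormad2 (2.79) among the higher ones. Over whole genes the median was 0.39, against 0.42 for spermatid and 0.22 for spermatogonial genes. Spermatid genes had 7 of 32 higher and 1 lower, with a median of 0.44 at percentile 13.1, and that median turned to -0.22 with windows of 5 or more CpGs set to 0, where 4 were higher and 3 lower. H1f7 (2.31, 1.87 to 2.79), Tnp1, a transition protein gene (2.23, 1.73 to 2.77), Spaca1 (2.58) and Tekt2 (1.80) were higher members. Spermatogonial genes had 2 of 19 higher, Utf1 (2.91, 2.04 to 4.09) and Sohlh2 (1.51), and 2 lower, with Lin28a at -1.49 (-2.09 to -0.95) and Stra8 neither at 0.90. Their median was 0.43, at percentile 20.04, and lay at -0.0073 with TMM and -0.24 with windows of 5 or more CpGs set to 0, where 1 was higher and 6 lower. Hormad2 had 0.070, Spaca1 0.17, Sohlh2 0.69 and Lin28a -0.88 over the whole gene, each under 2-fold, and Ccnb1ip1 had 1.09, Tekt2 1.14 and Rnf212 1.61. Sohlh2 had 3.26, H1f7 3.02 and Tekt2 2.80 with 500 bp on each side.

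Genes of piRNA and retrotransposon silencing were higher in 12 of 27 and lower in 1 (median 0.94, 0.68 to 1.98, percentile 99.9), with Mael at 2.96 (2.42 to 3.58), Gtsf1 at 3.29 and Morc1 at 2.26. Setdb1 had 0 wildtype counts and was at least 6.90-fold higher (log2 interval from 2.36). Over whole genes the list median was 0.28, with 0.51 for Mael, 0.56 for Setdb1, 0.67 for Gtsf1 and 0.13 for Morc1, which had 2.92 with 500 bp on each side. Among genes of the methylation machinery 4 of 22 were higher and 1 lower (median 0.46, percentile 24.6). With windows of 5 or more CpGs set to 0 the median was -0.21, and 2 were higher and 5 lower. Ctcfl, a germline paralogue of Ctcf, had 2.63 (2.17 to 3.17), Mbd2 2.06 (1.45 to 2.71), Zbtb4 1.49 and Mbd4 -2.33 (-3.95 to -1.09). Whole-gene values of these were 0.71, 0.32, 0.49 and -0.77, each under 2-fold, and Zbtb4 had 3.04 with 500 bp on each side. Replication-dependent histone genes were higher in 6 of 12 and lower in 1 (median 1.41, percentile 99.8), while 51 of the 68 in the list had no listed window. Among the higher ones were H2ac19 (5.14, 2.82 to 7.82), H1f6 (3.61), H2bc1 (3.01) and H2ac1 (2.92). The regions of H2bc1 and H2ac1 overlap on chromosome 13 and are not independent. The list median was 2.64 with 500 bp on each side and 0.51 over whole genes, and H2ac19 had 1.10 with 500 bp. Pluripotency genes were higher in 10 of 20 and lower in 3 (median 1.00, percentile 99.7), with Utf1, Zfp42 (2.82, 2.33 to 3.36), Tdgf1 (2.15) and Tcl1 (1.83) among the higher ones. With 500 bp on each side the list median was 1.63, and over whole genes it was 0.58, with 0.80 for Tdgf1, 1.08 for Tcl1 and 1.68 for Zfp42. Tdgf1 had 2.79 with 500 bp.

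Markers of testicular somatic cells went both ways. Sertoli cell genes had 7 of 21 higher and 2 lower (median 0.84, -0.32 to 1.81, percentile 98.6), among them Cst12 (4.61, 3.22 to 6.51), Amh, the anti-Müllerian hormone gene (3.09, 2.32 to 4.02), Rhox8 (2.76) and Tjp1 (3.92, 1.76 to 6.85). Tjp1 rested on 3 windows and had 1.42 with 500 bp on each side and 0.025 over the whole gene. The Sertoli median was 0.40 with TMM and 0.17 with windows of 5 or more CpGs set to 0, where 6 were higher and 5 lower, and over whole genes it was 0.48. Cst12 had 3.95 with 500 bp, and Rhox8 1.19 over the whole gene. Leydig cell genes had 3 of 11 higher and 2 lower (median 0.15, -1.41 to 2.26, percentile 17.1), and the median was -0.29 with TMM, -0.13 with autosomal counts and -0.52 with windows of 5 or more CpGs set to 0, where 2 were higher and 4 lower. With 500 bp on each side it was 1.98, and over whole genes 0.39. The hormone gene Insl3 had 4.40 (3.21 to 6.12), the receptor gene Lhcgr 2.26 (1.37 to 3.29), Cyp11a1 1.07 and Fads1 -1.41. Fads1 had 0.39, Lhcgr 0.53 and Cyp11a1 0.19 over the whole gene, and Cyp11a1 had 1.98 with 500 bp. Other somatic cell genes had 4 of 19 higher and 1 lower (median 0.58, percentile 67.4, but -0.087 with windows of 5 or more CpGs set to 0, where 2 were higher and 2 lower), with Col1a2 at 3.57 (1.59 to 6.70), Tek at 2.18, Kdr at 1.55 and the leukocyte gene Ptprc at -2.11 (-3.19 to -1.20). Over the whole gene these had 0.38, 0.46, 0.23 and -0.26, each under 2-fold, and Kdr had 0.33 with 500 bp on each side. The whole-gene median of this list was 0.28.

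Housekeeping genes had 1 of 22 higher and 4 lower, and their median of 0.0080 (-0.76 to 0.49) lay at percentile 0.63 of random lists, with -0.43 under TMM, -0.26 with autosomal counts, -0.100 within CpG classes and -0.66 with windows of 5 or more CpGs set to 0. Rplp0 had 2.22 (1.34 to 3.27), Ywhaz -1.83 (-2.79 to -0.98), Ppia -1.78 and Eno1 -1.58. Ywhaz had -0.21 and Eno1 -0.022 over the whole gene, and Rplp0 had 1.39. The housekeeping median was 0.19 with 500 bp on each side and 0.24 over whole genes, and with windows of 5 or more CpGs set to 0, 1 was higher and 8 lower. Genes reported as Kaiso targets had 5 of 23 higher and 4 lower (median 0.49, 0.25 to 0.77, percentile 38.8, but -0.18 with windows of 5 or more CpGs set to 0, where 1 was higher and 5 lower). Ctnnd1, the gene of the Kaiso partner p120 catenin, had 1.91 (1.58 to 2.26), Myc 1.47 (0.81 to 2.19), Bbc3 1.27 and Wnt11 -2.02 (-3.10 to -1.10). Over the whole gene Wnt11 had 0.67 and Ctnnd1 0.34, and with 500 bp on each side Bbc3 had 0.29 and Ctnnd1 2.85. Of 326 olfactory receptor genes 91 were higher and 100 lower (median 0.40, percentile 17.2, but -0.038 with TMM and -0.27 with windows of 5 or more CpGs set to 0), with Olfr1344 at 4.09, Olfr606 at 4.04 and Olfr117 at 3.89, and Olfr95 at least 11.1-fold higher against 0 wildtype counts (interval from 3.09). Of 241 Zfp genes 68 were higher and 34 lower (median 0.59, percentile 99.9, but -0.071 with windows of 5 or more CpGs set to 0), with Zfp703 at 4.08, Zfp474 at 3.61 and Zfp174 at least 11.6-fold higher against 0 wildtype counts (interval from 3.17). Zfp174 had 0.29 and Zfp474 0.80 over the whole gene, and Zfp174 had 1.86 with 500 bp. With the authors' scaling 100 olfactory receptor genes were higher and 83 lower. With windows of 5 or more CpGs set to 0, 62 olfactory receptor genes were higher and 129 lower, and 39 Zfp genes higher and 45 lower.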

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

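No paired analysis was possible because each genotype had 1 library, and calls rest on counting intervals between these libraries. Scaling by autosomal counts was the planned main scaling, and library reads took its place once the table was seen to hold part of each library. The authors' scaling, the scaling that sets windows of 5 or more CpGs to 0, undivided sums and whole genes were chosen after seeing the data. The motif comparison and its alternatives were not run, nor was a gene start told from a gene end. A constant scaling cannot move the X, Y or dense-against-poor ratios, so it says nothing of their stability. Of 66 checks of main values and counts 43 stayed within the counting interval or, for counts, within 1.5 times. So did 629 of 778 checks of named genes, and 124 of 160 checks of list medians stayed within the order-statistic interval. Among list medians whose interval spans 0, those of spermatogonial, Leydig and housekeeping genes crossed 0 under some scalings, and those of paternally imprinted and Sertoli cell genes stayed above 0 under each scaling run. Over whole genes 51 named genes moved, 4 turned and 43 stayed within their interval. Named genes turned in 5 checks: over the whole gene Zfp444 had 0.80, Dmrtc1c1 0.34, Fads1 0.39 and Wnt11 0.67, and with 500 bp on each side Ifi27l2a had 0.095. The 5 Zbtb33 windows without knockout reads rest on 81 wildtype counts, and low counts limit the lower regions most.

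Scaling within CpG classes shifts CpG-poor windows up and dense ones down by construction. It gave 189639 higher and 35838 lower bins, 5940 higher and 459 lower gene-end regions, -1.24 for Zbtb33, 0.029 for X, 0.12 for Y, -0.15 for dense against poor bins, and 11 lists with a median of at least 1 in place of 7. List medians were 0.81 for spermatogonial, 0.62 for spermatid, 0.82 for Kaiso target, 0.72 for olfactory receptor and 0.93 for Zfp genes. Setting windows of 5 or more CpGs to 0 gave 39517 higher bins, and 1980 higher and 3206 lower gene-end regions. The list medians were then 1.93 for maternally imprinted, -0.22 for spermatid, -0.087 for other somatic, -0.18 for Kaiso target, 0.27 for piRNA, -0.21 for methylation machinery, 0.33 for pluripotency, -0.27 for olfactory receptor, 1.64 for Rhox and -0.071 for Zfp genes. With TMM they were 0.0078 for spermatid, 0.052 for Kaiso target, 0.50 for piRNA, 0.025 for methylation machinery, -0.038 for olfactory receptor, 1.88 for Rhox and 0.16 for Zfp genes. Autosomal counts gave 0.17 for spermatid, 0.21 for Kaiso target, 0.66 for piRNA, 0.19 for methylation machinery, 0.12 for olfactory receptor and 0.32 for Zfp genes. The authors' scaling gave 0.53 for olfactory receptor and 0.72 for Zfp genes. These 4 scalings move all genes by 1 constant, which is the cause of the moves.

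A ratio of at least 1.5 gave 149398 higher bins and 5877 higher gene-end regions, as a wider call must. A minimum of 50 fragments left 50086 lower bins and 992 lower gene-end regions, as fewer regions qualified. Undivided sums gave 318342 lower bins and 3151 lower gene-end regions, through narrower intervals and more regions with the minimum. Without the 0.1% of windows with the highest counts X had 0.20 and Y 0.41, and the cause was not tested. Whole genes gave 1854 higher and 1097 lower regions and 4 lists with a median of at least 1, with medians of 1.09 for maternally imprinted, 0.73 for germline, 0.39 for meiotic, 0.28 for piRNA and 0.38 for Zfp genes. With 500 bp on each side the meiotic median was 2.59. The cause was not tested for either region size.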

Other observations

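All tests of explanations here, and the gene families and runs of bins named, were chosen after the results were seen. Genes were grouped into 162 families by the stem of the symbol, so some percentiles near 0 or 100 among random lists arise by chance. Random lists were matched on fragments only, not on CpG content or on clustering, and members of a clustered family are not independent. Named here are the 6 lowest medians, and the families with a median of at least 1 that are not protocadherin or Rhox genes. Claudin genes (Cldn) were higher in 15 of 26 and lower in 1, with a median log2 ratio of 1.19 (percentile 99.98), Lypd genes in 7 of 10 (1.40, percentile 99.67) and Btbd genes in 31 of 40 (1.99, percentile 100). Trace amine receptor genes (Taar) were higher in 6 of 11 and lower in 3 (1.40, percentile 99.44), and Tnfsf genes higher in 6 of 10 and lower in 1 (1.16, percentile 97.94). Families of the opposite direction were Apol genes, with 6 of 11 lower and 0 higher (median -1.24, percentile 0.06), lipocalin genes (Lcn), with 5 of 10 lower and 0 higher (-1.14, percentile 1.63), taste receptor genes (Tas), with 8 of 12 lower and 2 higher (-1.33, percentile 1.17), and vomeronasal receptor genes (Vmn), with 16 of 41 lower and 6 higher (-0.81, percentile 0.67). Pramel genes, with 7 of 17 lower and 2 higher, had a median of -0.87 (percentile 2.58), and Tmprss genes, with 4 of 12 lower and 1 higher, of -0.74 (percentile 0.11). The medians of these families kept their sign under each other scaling. Within CpG classes, however, 11 Vmn genes were higher and 6 lower, 4 Pramel genes higher and 3 lower, 3 Tas genes higher and 4 lower, and 1 Apol gene higher and 0 lower. Of Lcn and of Tmprss genes 1 was then higher and 1 lower, and the Tmprss median was -0.020. With windows of 5 or more CpGs set to 0, 3 Tnfsf genes were higher and 3 lower. On X, an 8 kb run from 169991001 had a log2 ratio of 5.20 (4.74 to 5.66), close to the 13 kb run over Mid1 with -1.72. A 14 kb run over Flg, the filaggrin gene, on chromosome 3 from 93280001 had 2.23, and a 10 kb run over Ahnak2 on chromosome 12 from 112775001 had 1.52.

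In windows with 5 or more CpGs the level of most lists lay far below the median of all such listed windows in wildtype and nearer to it in the knockout library. Against that median RPKM, 7.98 in wildtype and 12.2 in the knockout, maternally imprinted gene ends stood at 5.71% and 33.3%, Hox genes at 2.86% and 22.5%, protocadherins at 7.14% and 44.2%, Rhox genes at 5.71% and 32.5%, and Sertoli cell genes at 3.57% and 25.4%. Leydig cell genes stood at 1.43% and 31.7%, other somatic cell genes at 7.14% and 40%, and Kaiso targets at 11.4% and 50.8%. Olfactory receptor genes stood at 24.3% and 74.6% and Zfp genes at 25.7% and 69.2%, so this is not particular to the lists named first. Spermatid genes stood at 62.9% and 82.5%, methylation machinery genes at 77.1% and 82.1%, and housekeeping genes at 86.4% and 77.1% over 16 windows. These windows were listed because the libraries differ there.

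Germline, maternally imprinted, Hox and protocadherin gene ends were higher in the knockout library. Removing a shift in capture by 1 factor for all windows of the same CpG count left these medians high. Scaling within CpG classes removes such a factor: the maternally imprinted, germline, Hox and protocadherin medians were then 2.54, 2.27, 2.63 and 2.71. The lowest of their lower bounds, which treat genes of a cluster as independent, exceeded the median of all gene-end regions by 0.705. As log2 values, the factors were -1.22 with 1 CpG and -0.71 with 2 CpGs. They ran from 0.51 with 3 CpGs to 0.78 with 10, and reached 1.71 with 11 or more. As the lists were picked for high medians, that outcome was largely set beforehand. The factors are also medians of windows selected on p, so the outcome does not decide whether such a shift contributes. A change in capture that acts most on weakly captured dense windows is not removed by this scaling and was not tested. A different cell makeup, with fewer germ cells in the tissue of a sterile male, stays open as a candidate explanation. Lists outside the pattern did not decide it, as they differed with the list used. The spermatid median lay at percentile 13.1 of random lists, with an interval that spans their median, and the spermatogonial median at 20.04. The meiotic median lay at percentile 100, and that of piRNA and retrotransposon silencing genes at 99.9. Loss of Kaiso in the cells themselves cannot be told apart from a different cell makeup, because genotype and cell makeup go together with 1 library each. The median of reported Kaiso targets lay at percentile 38.8 of random lists. Histology, or methylation of sorted cells, would separate them, and a tissue other than the one labelled was not tested.

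Windows with 5 or more CpGs were higher in the knockout library by a small factor, with a median log2 ratio of 0.666. Less carry-over of unmethylated DNA into the knockout library may contribute, as 29 of 30 listed mitochondrial windows were lower there, although mitochondrial content per cell could differ too. Counts of windows without a read are mixed. Runs of at least 5 adjacent listed windows without a read numbered 1322 in wildtype and 202 in the knockout. More carry-over in wildtype would leave wildtype reads there. Listed windows without a read, in runs or not, numbered 31585 in wildtype and 37953 in the knockout library. These windows were listed because the libraries differ, so neither count measures carry-over by itself. The question is not decided here. A gain of methylation across the genome cannot be told apart from a change in capture in this table, because windows with a ratio near 1 are not listed.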
